A study of Homo sapiens with 8 samples.

How the data were processed

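RNA from MM1.S and NCI-H929, established human multiple myeloma cell lines, was hybridised to Affymetrix Human Gene ST arrays. Each line carried either a scramble short hairpin construct or a construct against SIRT6, an NAD-dependent deacetylase of chromatin, and each of the 4 combinations has 2 arrays, 8 in all. Array groups were taken from the cell line and condition labels, and replicate numbers from the titles. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical only.

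The deposited values are on a log2 scale, printed to 2 decimals, 1 row per transcript cluster, and per the submitters' processing notes the authors used RMA, the Transcriptome Analysis Console and the hg19 build. RMA normally subtracts background, quantile normalizes and summarises probes. Its variant, the software versions and the scan dates are not given in the sources used here. Scanner intensities were not used here, so no probe could be judged against its background. The table holds 48226 rows, of which 16098 carry 1 gene symbol in the platform annotation, none carries several and 32128 are unnamed here. The named rows cover 14884 distinct symbols. All 8 columns were used and no other column of per-sample values was present (0). Order of the genes along chromosomes, used for 1 observation, came from the RefSeq annotation of assembly GRCh38.p14 and no coordinates are printed.

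For each gene the cluster with the highest mean over the 8 arrays was kept, which mattered for 779 genes with over 1 row. Genes with a mean above the 30th percentile of all clusters, a log2 level of 3.045, were tested, 12734 in all. limma 3.58.1 in R 4.3.3 fitted 4 group means to all 8 arrays together (lmFit, then eBayes), with 4 residual degrees of freedom, 3.43 prior degrees of freedom and a prior SD of 0.128. The contrasts were shSIRT6 minus scramble in MM1.S, the same in NCI-H929, their mean, their difference (NCI-H929 minus MM1.S) and NCI-H929 minus MM1.S with the scramble construct. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested. Fold changes are log2 differences with limma's standard error (SE). No exact permutation test of 2 arrays against 2 can give a two-sided p below 0.333, so single genes rest on limma alone. The number of arrays limits the precision.

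Gene lists were fixed before the data were examined, 33 in all, as were the contrasts, the filter, the rule for named genes and the alternatives, except where a test is said to have been chosen later. A list was tested if at least 5 members had a named row that passed the filter, which left 29. The lists of the proteasome (0 tested members), B cell markers (4), stromal markers (3) and replication-dependent histones (1) were not tested. Members without a named row could not be tested, so an untested member need not be low in level. Several lists were tested only in part. Of the fixed symbols, 9 of 24 were tested for glycolysis, 13 of 44 for oxidative phosphorylation and 16 of 29 for the ATF4 list. The shares were 22 of 38 for DNA replication, 20 of 35 for double-strand break repair, 46 of 78 for ribosomal proteins and 49 of 69 for the spliceosome core. limma's camera compared the members with all other genes, with a preset correlation between members of 0.01 and, as an alternative, with a correlation estimated for each list; fry was a further alternative. List p-values were adjusted over the 29 lists of a contrast. Counts of members called are given over all genes tested and adjusted over the list alone.

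Named genes are SIRT6; per line the 8 largest rises and the 8 largest falls among the called genes whose arrays of the 2 constructs do not overlap; for the mean, the 8 largest of each direction with one sign in both lines; for the difference, the 5 of each sign with the lowest p; for the lines themselves, the translocation genes and the 5 largest differences each way; and up to 4 members, by lowest p, of each list that passed and of the splicing, glycolysis, repair and plasma cell lists. MicroRNAs, other noncoding RNAs known by their symbols, immunoglobulin and T cell receptor segments, provisional symbols and XIST were not named by this rule. Genes named outside this rule are said to be so.

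The fitting code was tested on simulated arrays of 12734 genes with a seeded set of changed genes. In MM1.S it recovered 13.4% of changes of 0.5 log2, 76.1% of changes of 1 and 84.8% of changes of 1.5, with 8 false calls among 124. In NCI-H929 the shares were 14.9%, 71.6% and 87.9%, with 7 false calls among 123. Of unchanged genes, 5.00% and 4.85% had an unadjusted p below 0.05. Lists of unchanged genes passed at an unadjusted p below 0.05 in 3% and 1% of draws, and shifted lists in 100% in both lines. Simulated genes varied independently, with the spread that limma's own model assumes and no trend with level. These shares therefore check the code and do not measure the error for real lists, whose members may vary together.

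The alternatives were the replicate number as a block, each line fitted alone, quantile, median and cyclic loess normalization, no filter and a filter at the 60th percentile, the mean of a gene's clusters, every cluster named or not, eBayes with trend and robust options, array weights, an unadjusted p below 0.05 with a 1.5-fold change, limma's treat against a 1.2-fold change, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.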

Results

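The data comprise 8 arrays of 2 multiple myeloma cell lines, MM1.S and NCI-H929, each with a scramble construct or a short hairpin against SIRT6 (shSIRT6), 2 arrays per group. The study's title concerns loss of SIRT6 in myeloma and the splicing machinery, so the lists of splicing genes are given for every comparison. Median log2 levels per array ran from 3.88 to 3.97 over all clusters. Arrays of one group correlated at 0.989 to 0.992 across clusters, arrays of one line with different constructs at 0.985 to 0.989, and arrays of different lines at 0.942 to 0.950. No pair of arrays was close to a duplicate, since at most 1.96% of values were equal to 2 decimals.

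SIRT6, the target of the hairpin, was read by 1 cluster (16867260). In MM1.S its log2 level was 6.09 and 5.88 with scramble and 5.60 and 5.78 with shSIRT6. In NCI-H929 it was 6.53 and 6.97 with scramble and 6.25 and 6.31 with shSIRT6. Both shSIRT6 arrays of a line lay below both scramble arrays, but the differences did not pass the test: the log2 difference was −0.30 ± 0.16 (SE) in MM1.S and −0.47 ± 0.16 in NCI-H929 (limma, Benjamini-Hochberg adjusted p = 0.355 and 0.276). Without scramble replicate 1 of MM1.S the difference there was −0.19, and without scramble replicate 2 of NCI-H929 it was −0.25. Averaged over both lines it was −0.38 ± 0.11 (adjusted p = 0.135). The groups of 2 arrays therefore check the construct labels only weakly, most of all in MM1.S.

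**Figure D1:**
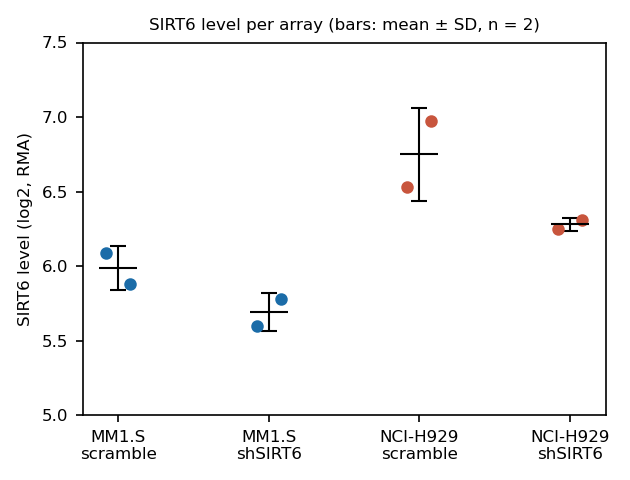
SIRT6 level (log2, RMA) on each of the 8 arrays, by line and construct; points are arrays and bars the mean ± SD of 2 arrays. In each line both shSIRT6 arrays lie below both scramble arrays, from 5.60 against 6.09 at the widest in MM1.S and from 6.25 against 6.97 in NCI-H929.

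With the scramble construct the lines differed in the tested genes of the myeloma translocation list, 7 of 10 fixed ones. MAF, a transcription factor translocated in MM1.S, was lower in NCI-H929 by a log2 difference of −1.46 ± 0.12 (SE), and CCND2 (cyclin D2) by −2.54 ± 0.099. FGFR3, a receptor tyrosine kinase, and NSD2, a histone methyltransferase, which share a translocation in NCI-H929, were higher there by 2.04 ± 0.13 and 1.38 ± 0.093. CCND1 (cyclin D1) was also higher in NCI-H929, by 2.56 ± 0.11, and CCND3 by 0.41 ± 0.12, while CX3CR1 was lower by −0.61 ± 0.16. All 7 passed (limma, Benjamini-Hochberg adjusted p from 2.69e-06 for CCND2 to 0.0315 for CCND3). The directions of MAF, FGFR3 and NSD2 go with the line labels. The other genes of the list do not check the labels here. Among the largest differences, PURPL (6.95), NES (nestin, 6.12), FCRL2 (5.33), TSSC2 (5.28) and LAPTM4B (5.19) were higher in NCI-H929. LAPTM5, a lysosomal membrane protein of blood cells, was lower there by −8.16. QPCT, SYCP3, POGLUT2 and STAP1 had mean levels of 9.31, 8.50, 8.27 and 7.98 in MM1.S but 2.97, 2.81, 2.72 and 2.46 in NCI-H929, all under the filter level of 3.045. Their log2 differences of −6.34, −5.69, −5.56 and −5.52 therefore depend on probes that may not be above background there, and their order was not resolved. Altogether 4875 of 12734 genes differed, 2543 higher and 2332 lower in NCI-H929. Calls were lost for CCND3 in 8 of 20 alternatives and for CX3CR1 in 6 of 19.

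In MM1.S, genes of the amino acid response fell with shSIRT6. This is the program that the transcription factor ATF4 drives when amino acids are short or the endoplasmic reticulum is stressed. Of 16 tested members of that list 13 fell and none rose (0), and 15 fell when adjusted over the list alone; the median log2 change was −0.97. ASNS, which makes asparagine, fell by 1.31 ± 0.092 (SE) on the log2 scale, SARS1, the seryl-tRNA synthetase, by 1.21 ± 0.092, SESN2, an inhibitor of mTORC1 signalling, by 1.21 ± 0.10, and PSAT1, an enzyme of serine synthesis, by 0.99 ± 0.088 (limma, Benjamini-Hochberg adjusted p = 0.00377, 0.00452, 0.00599 and 0.00806). The other members that fell, listed here after their values were seen, were the stress regulators DDIT3 (CHOP) and TRIB3, the enzymes PHGDH, SHMT2, CTH, CBS and PCK2, the tryptophanyl-tRNA synthetase WARS1 and the lipoprotein receptor VLDLR. ATF4 itself changed by −0.23 ± 0.091, which did not pass (adjusted p = 0.233). The list stood apart from other genes (camera adjusted p = 1.79e-17, and adjusted p = 0.0195 with an estimated correlation).

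**Figure D2:**
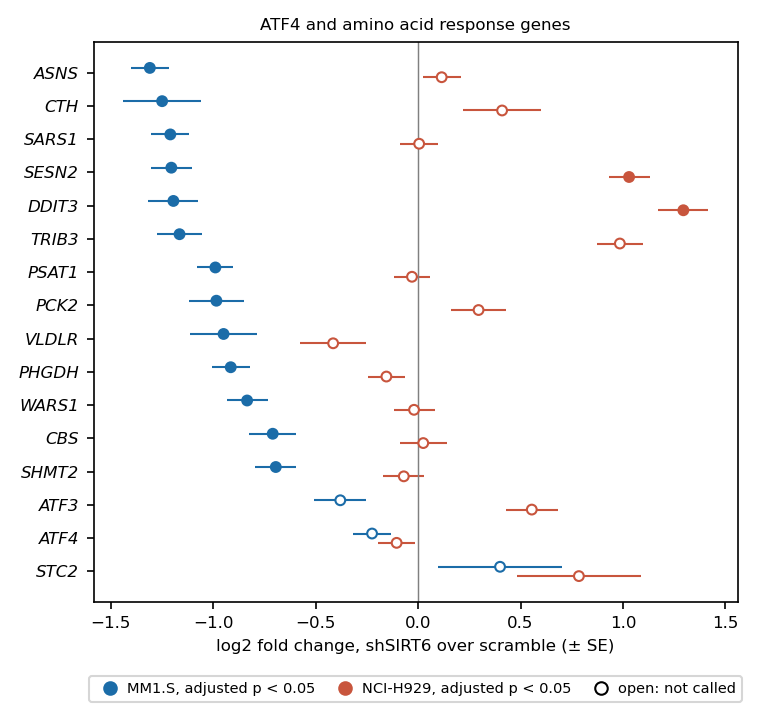
Log2 fold change of shSIRT6 over scramble, with its standard error, for the 16 tested members of the ATF4 and amino acid response list in MM1.S (blue) and NCI-H929 (red), 2 arrays per group; filled points passed limma at an adjusted p below 0.05. The median is −0.97 in MM1.S, where 13 members fell, and 0.07 in NCI-H929, where DDIT3 and SESN2 rose.

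Beyond that list, and with microRNAs left out, large falls in MM1.S were seen in PIERCE2, a protein of ciliary microtubules (log2 change −1.97 ± 0.19, SE), CCDC144CP (−1.87 ± 0.17) and PLXDC2 (−1.86 ± 0.12). Others were in DDIT4, a further inhibitor of mTORC1 (−1.43 ± 0.098), ALOX5AP, which serves leukotriene synthesis (−1.40 ± 0.093), RNF148 (−1.39 ± 0.10), EFEMP1 (−1.38 ± 0.14) and CALCRL (−1.32 ± 0.13). PIERCE2 and RNF148 each lie beside another gene that fell, and CCDC144CP is a pseudogene whose probes may read its near-identical copies. Rises were smaller. MIDN (midnolin) rose by 1.01 ± 0.13, KLHL29 by 0.94 ± 0.11, SYN1 (synapsin) by 0.93 ± 0.11, CIMAP1D by 0.91 ± 0.14, TP73, a relative of p53, by 0.85 ± 0.12, CDC42EP4 by 0.84 ± 0.12, the dopamine receptor DRD3 by 0.82 ± 0.14 and ARHGAP17 by 0.72 ± 0.092. Adjusted p over these 16 genes ran from 0.00377 to 0.0468 (limma, Benjamini-Hochberg). Several rises started near the filter level of 3.045: mean log2 levels with scramble were 3.63 for KLHL29, 3.69 for DRD3 and 3.91 for SYN1. They were 4.24 for CIMAP1D, 4.42 for TP73, 4.545 for CDC42EP4, 5.42 for MIDN and 7.195 for ARHGAP17. Calls were lost in 16 of 20 alternatives for DRD3, 12 of 20 for TP73 and 12 of 21 for CIMAP1D. For the other rises they were lost in 8 to 10 of 21, and for these falls in 4 to 6.

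Other gene groups moved less in MM1.S. The cholesterol synthesis list rose as a set, with 12 of 17 members positive and a median of 0.24 (camera adjusted p = 0.0175, and adjusted p = 0.372 with an estimated correlation). None of its members was called (limma, 0 over all genes and 0 adjusted over the list alone; 8 had an unadjusted p below 0.05). MSMO1 had the lowest p, at 0.43 ± 0.11. Leaving out replicate 1 of scramble or of shSIRT6 in MM1.S ended the list's call (camera adjusted p = 0.0524 and 0.0625). The unfolded protein response list fell as a set (median −0.15, adjusted p = 0.0175, and adjusted p = 0.276 with an estimated correlation). Cyclic loess normalization ended that call (adjusted p = 0.0748, median −0.12), as did leaving out scramble replicate 2 (0.0754) or shSIRT6 replicate 2 (0.0511) of MM1.S. In it 1 of 16 members was called, SEL1L of the degradation machinery (−0.54 ± 0.093), and 3 when adjusted over the list alone, while ERN1 (−0.46), DERL2 (−0.35) and ATF6 (−0.29) were not called over all genes. Small nuclear, nucleolar and Cajal body RNAs fell as a set (median −0.19 over 23 members, adjusted p = 0.0175, and adjusted p = 0.276 with an estimated correlation), with 0 called, 3 when adjusted over the list alone, and 5 at an unadjusted p below 0.05. The stricter filter ended this call (camera adjusted p = 0.111), as did leaving out scramble replicate 1 (0.0524) or shSIRT6 replicate 2 (0.0511) of MM1.S. The splicing lists did not pass. For the 49 spliceosome core genes the median was −0.02 (camera adjusted p = 0.871) and for the 42 SR proteins and hnRNPs −0.02 (adjusted p = 0.871). No member of either was called (limma, 0 and 0; 8 and 7 at an unadjusted p below 0.05). Members with the lowest p went both ways, from BCAS2 (−0.59 ± 0.14) and PLRG1 (−0.40 ± 0.097) to HNRNPL (0.37 ± 0.088) and PTBP1 (0.34 ± 0.093). In lists that did not pass, PARP2, a DNA-break sensor of base excision repair, fell by 0.73 ± 0.10 on the log2 scale (adjusted p = 0.0263), and SDC1, the plasma cell marker CD138, rose by 0.52 ± 0.091 (adjusted p = 0.0461). The calls of SEL1L, SDC1 and PARP2 were lost in 16, 14 and 10 of 21 alternatives.

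Over all genes, 169 of 12734 were called in MM1.S, 26 higher and 143 lower. At an unadjusted p below 0.05 there were 2493, where 637 would come by chance, split more evenly into 1051 higher and 1442 lower. Leaving out any 1 array lowered the count, to 0 at the least (without scramble replicate 1 or shSIRT6 replicate 2 of MM1.S) and 84 at the most, and fitting MM1.S alone gave 0 calls (limma; 2275 at an unadjusted p below 0.05).

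In NCI-H929, 3 genes were called. DDIT3 (CHOP), a transcription factor of stress-induced death, rose by 1.30 ± 0.12 (SE) on the log2 scale and SESN2 by 1.03 ± 0.10, while CCND2 fell by 1.08 ± 0.099 (limma, Benjamini-Hochberg adjusted p = 0.0484 for each). The ATF4 and amino acid response list rose as a set (camera adjusted p = 0.00116, and adjusted p = 0.183 with an estimated correlation), with a median of 0.07, 10 of 16 members positive, 2 called and 4 when adjusted over the list alone. Over the alternatives that median ran from 0.06 to 0.14, the highest after cyclic loess normalization. TRIB3 (0.99 ± 0.11) and ATF3 (0.56 ± 0.13) were not called over all genes. Each of the 3 calls was lost in 16 of 21 alternatives, and CCND2 went to −0.64 when its clusters were averaged.

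Cell cycle genes were lower in NCI-H929 as sets. All 31 tested members of the mitosis list were negative, with a median of −0.28 (camera adjusted p = 2.19e-10, and adjusted p = 0.0795 with an estimated correlation). Quantile normalization brought that median to −0.18. None was called over all genes (limma, 0; 19 at an unadjusted p below 0.05) and 16 fell when adjusted over the list alone, with the phosphatase CDC25C at −0.45 ± 0.096, the kinesin KIF20A at −0.46 ± 0.098 and CDC20 at −0.35 ± 0.092. All 22 tested members of the DNA replication list, of 38 fixed, were negative too, with a median of −0.36 (camera adjusted p = 2.19e-10, and adjusted p = 0.183 with an estimated correlation). There 0 were called, 15 had an unadjusted p below 0.05 and 15 fell when adjusted over the list alone, among them GINS2 (−0.71 ± 0.13), the licensing factor CDC6 (−0.52 ± 0.099), thymidylate synthase TYMS (−0.49 ± 0.093) and RRM2 (−0.43 ± 0.092). Myeloma translocation genes fell as a set of 7 (median −0.18, adjusted p = 0.0137, and adjusted p = 0.183 with an estimated correlation), with CCND2 called, 2 when adjusted over the list alone, CCND1 at −0.68 ± 0.11 and FGFR3 at −0.38 ± 0.13. Leaving out shSIRT6 replicate 2 of NCI-H929 ended this call (camera adjusted p = 0.0589), and the median ran from −0.28 with the stricter filter to −0.10 after cyclic loess normalization.

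Splicing genes were slightly lower in NCI-H929. Of 49 spliceosome core genes 41 were negative, with a median of −0.12 (camera adjusted p = 0.00982, and adjusted p = 0.273 with an estimated correlation). Of 42 SR proteins and hnRNPs 37 were negative, with a median of −0.11 (adjusted p = 0.00779, and adjusted p = 0.299 with an estimated correlation). No gene of either list was called over all genes or adjusted over the list alone (limma, 0 and 0; 4 and 5 at an unadjusted p below 0.05). Those with the lowest p were SNRPB, a core snRNP protein (−0.42 ± 0.095), SNRPA (−0.32 ± 0.093), the RNA-binding protein PCBP2 (−0.42 ± 0.11) and HNRNPH1 (−0.32 ± 0.099). Cyclic loess normalization ended both calls (adjusted p = 0.689 for each) and left medians of −0.04 and −0.03; quantile normalization, the stricter filter and leaving out scramble replicate 1 of NCI-H929 (camera adjusted p = 0.0579 and 0.0591) ended them as well, and leaving out shSIRT6 replicate 2 ended that of the spliceosome core (0.0589).

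Other sets in NCI-H929 were lower by similar amounts, with no member called over all genes. They were ribosomal proteins (41 of 46 negative, median −0.14, camera adjusted p = 0.00145, and adjusted p = 0.183 with an estimated correlation), double-strand break repair (19 of 20, median −0.16, adjusted p = 0.00244, and adjusted p = 0.183 with an estimated correlation), heat shock (9 of 9, median −0.17, adjusted p = 0.00837, and adjusted p = 0.299 with an estimated correlation) and base excision repair (14 of 16, median −0.15, adjusted p = 0.0424, and adjusted p = 0.391 with an estimated correlation). Adjusted over the list alone, limma called 0, 1, 2 and 0 of their members, and 8, 5, 3 and 4 had an unadjusted p below 0.05. Examples were RPS15A (−0.59 ± 0.14), TP53BP1, which guides repair of double-strand breaks (−0.70 ± 0.12), the near-identical chaperone genes HSPA1A (−0.59 ± 0.12) and HSPA1B (−0.56 ± 0.12), and the flap nuclease FEN1 (−0.34 ± 0.097). Cyclic loess normalization ended all 4 of these calls. That of heat shock was also lost without scramble replicate 1 (camera adjusted p = 0.118) or shSIRT6 replicate 2 (0.0668) of NCI-H929, and that of base excision repair in 11 of 22 alternatives. Markers of T and NK cells, a list kept as a check for foreign RNA, were higher (7 of 7 positive, median 0.28, adjusted p = 0.00779, and adjusted p = 0.183 with an estimated correlation; 0.0709 after cyclic loess), with none called (limma, 0 over all genes and adjusted over the list alone; 1 at an unadjusted p below 0.05) and CD4 at 0.55 ± 0.21. These markers had a low mean log2 level of 4.34. Of 10000 random lists of genes matched on level, 9748 had a median as low. Level could therefore account for this rise, and it is no clear sign of foreign RNA.

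**Figure D3:**
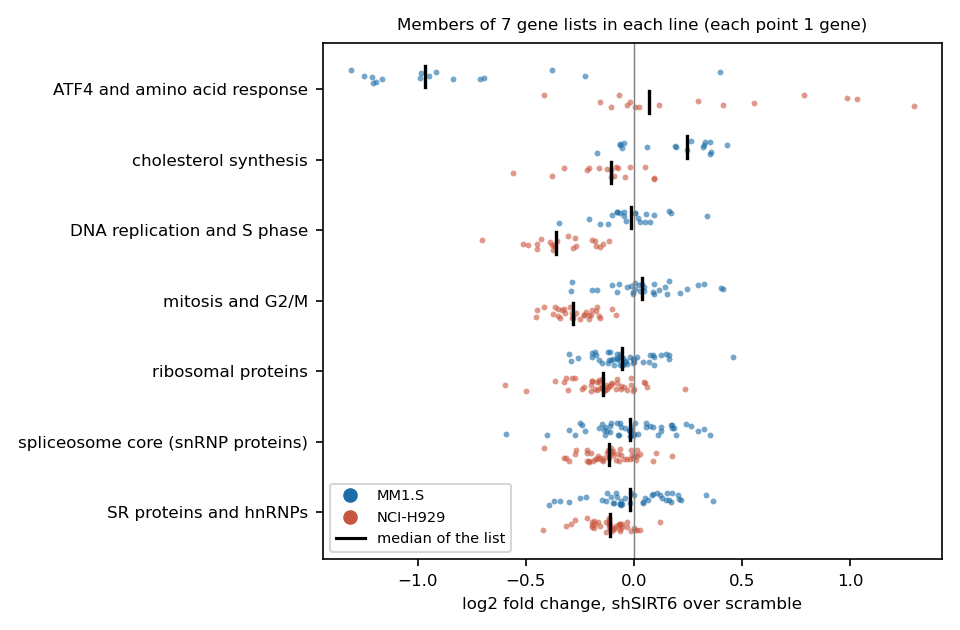
Log2 fold change of shSIRT6 over scramble for each tested member (points) of 7 gene lists in MM1.S (blue) and NCI-H929 (red), with the list's median as a black line. The ATF4 and amino acid response genes sit around −0.97 in MM1.S and 0.07 in NCI-H929, and the mitosis genes are all below 0 in NCI-H929, with a median of −0.28.

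Glycolysis and plasma cell genes passed in neither line. Glycolysis had a median of 0.02 over 9 genes in MM1.S and −0.14 in NCI-H929 (camera adjusted p = 0.715 and 0.166), with LDHA at 0.12 ± 0.10 and −0.15 ± 0.10. Plasma cell identity genes had medians of −0.02 and −0.07 over 16 genes (adjusted p = 0.918 and 0.554), with IRF4, a survival factor of myeloma cells, at −0.33 ± 0.090 in MM1.S and MZB1 at −0.20 ± 0.090 in NCI-H929, neither called.

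The response to shSIRT6 differed between the lines, and genes of the ATF4 list were among those that differed most. NCI-H929 minus MM1.S, the log2 effect differed by 2.49 ± 0.17 (SE) for DDIT3, 2.24 ± 0.14 for SESN2, 2.15 ± 0.16 for TRIB3, 1.43 ± 0.13 for ASNS and, outside the list, 2.16 ± 0.14 for DDIT4 (limma, Benjamini-Hochberg adjusted p from 0.00386 to 0.0170). CCND2 went the other way (−1.21 ± 0.14, adjusted p = 0.0371). Its call was lost in 12 of 20 alternatives, against 1 to 9 of 20 for the other genes named here, and its smallest value was −0.805. With the mean of clusters, 25 differences were called higher in NCI-H929 and 0 lower. All 16 tested members of the ATF4 list had a positive difference, with a median of 0.95 (camera adjusted p = 1.81e-22, and adjusted p = 0.0119 with an estimated correlation). Of them, 6 were called over all genes and 13 when adjusted over the list alone. Within the list the members differed in NCI-H929: DDIT3 and SESN2 rose there, whereas ASNS (0.12), PSAT1 (−0.03), PHGDH (−0.16), SARS1 (0.01) and WARS1 (−0.02), examples chosen after their values were seen, were not called.

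Cell cycle and cholesterol genes differed between the lines as sets as well. Relative to MM1.S, the effect in NCI-H929 was lower for mitosis (median −0.30, camera adjusted p = 2.68e-08, and adjusted p = 0.0630 with an estimated correlation), DNA replication (−0.32, adjusted p = 5.26e-06, and adjusted p = 0.329 with an estimated correlation), cholesterol synthesis (−0.32, adjusted p = 0.00274, and adjusted p = 0.234 with an estimated correlation) and translocation genes (−0.41, adjusted p = 0.00707, and adjusted p = 0.234 with an estimated correlation). Adjusted over the list alone, limma called 5, 7, 0 and 2 of their members (7 cholesterol genes had an unadjusted p below 0.05); over all genes CCND2 was the single one. MKI67, the proliferation marker Ki-67, differed by −0.74 ± 0.13 and the licensing factor CDT1 by −0.79 ± 0.20, neither called. The splicing lists did not pass this test (spliceosome core median −0.10, adjusted p = 0.153; SR proteins and hnRNPs −0.11, adjusted p = 0.0781).

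In total 26 genes differed in their response, 25 with a more positive effect in NCI-H929 and 1 with a more negative one. That split belongs to these calls: at an unadjusted p below 0.05 it was 730 against 1033, and with the trend and robust options 199 against 225. Of the 169 genes called in MM1.S, 96 had the same sign in NCI-H929 and 71 the opposite sign, and 24 were among the 26. DDIT3 and SESN2 were the 2 genes called in both lines, in opposite directions. Across the 12734 genes, which are not independent replicates, the log2 changes of the lines correlated weakly (Pearson's r = 0.163, Spearman's rho = 0.191). Leaving out 1 array left 2 to 6 of these 26 calls in number.

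Averaged over both lines, 11 genes were called, all lower with shSIRT6. PLXDC2 fell by 1.05 ± 0.084 (SE) on the log2 scale, RNF148 by 0.92 ± 0.072 and MERTK, a receptor tyrosine kinase, by 0.79 ± 0.078. TOM1L1 fell by 0.72 ± 0.079, ZNF519 by 0.69 ± 0.081, RHOBTB3 by 0.65 ± 0.074, DNAAF4-CCPG1 by 0.63 ± 0.063 and SKIL, a repressor of TGF-beta signalling, by 0.62 ± 0.066 (limma, Benjamini-Hochberg adjusted p from 0.0187 to 0.0473). Most of these averages came mainly from MM1.S. PLXDC2 was at −1.86 in MM1.S against −0.25 in NCI-H929 and DNAAF4-CCPG1 at −1.14 against −0.11, and both were called as differing between the lines (adjusted p = 0.0243 and 0.0412). In NCI-H929 the log2 change was −0.46 for RNF148, −0.39 for MERTK, −0.38 for SKIL and −0.32 for RHOBTB3, each under its MM1.S value in size. TOM1L1 (−0.67 in MM1.S and −0.76 in NCI-H929) and ZNF519 (−0.67 and −0.72) were of similar size in both lines, although neither was called in NCI-H929. The other 3 calls were ALOX5AP, ASNS and SARS1, whose log2 changes in NCI-H929 were 0.03, 0.12 and 0.01.

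As sets, 10 lists were lower on average, and none passed with an estimated correlation. DNA replication (median −0.18, camera adjusted p = 5.09e-05, and adjusted p = 0.253 with an estimated correlation), the ATF4 list (−0.36, adjusted p = 1.78e-05, and adjusted p = 0.171 with an estimated correlation), double-strand break repair (−0.17, adjusted p = 0.00240, and adjusted p = 0.226 with an estimated correlation) and mitosis (−0.09, adjusted p = 0.00693, and adjusted p = 0.226 with an estimated correlation) were among them. The others were ribosomal proteins (−0.10), small nuclear and nucleolar RNAs (−0.16) and the unfolded protein response (−0.12), each at an adjusted p = 0.226 with an estimated correlation, and heat shock (−0.17), base excision repair (−0.11) and hypoxia (−0.18), each at an adjusted p = 0.398 with an estimated correlation. Adjusted over the list alone, limma called 6 replication genes, 11 lower and 1 higher ATF4-list genes, 5 lower and 1 higher hypoxia genes, 4 heat shock genes, 3 break repair genes, 2 mitosis genes, 2 base excision repair genes and 0 of the ribosomal, small RNA and unfolded protein response lists (7, 9 and 6 at an unadjusted p below 0.05). Mitosis and DNA replication had medians of 0.04 and −0.02 in MM1.S, with 20 of 31 and 11 of 22 members positive, so their averages reflect NCI-H929. The ATF4 list fell in MM1.S (median −0.97) and rose slightly in NCI-H929 (median 0.07, 10 of 16 members positive). That rise did not pass with an estimated correlation (camera adjusted p = 0.183). Double-strand break repair had negative medians in both lines (−0.14 in MM1.S and −0.16 in NCI-H929). Quantile and cyclic loess normalization each ended the calls of mitosis (median −0.03 both times), ribosomal proteins (−0.03 and −0.04), the unfolded protein response, heat shock, base excision repair and hypoxia (camera adjusted p from 0.173 to 0.422 after loess). The stricter filter ended these as well as those of break repair (0.0562) and small RNAs (0.111). CDC6 stood at −0.36 ± 0.070, TP53BP1 at −0.43 ± 0.083 and PARP2 at −0.50 ± 0.071, none of them called over all genes. Splicing lists did not pass on average (median −0.10 and −0.07, adjusted p = 0.0819 and 0.225), with BCAS2 at −0.38 ± 0.098 and SRPK2, a kinase of SR proteins, at −0.34 ± 0.069. Leaving out any 1 array ended all 11 gene calls (limma, 0; 1877 to 2693 genes at an unadjusted p below 0.05).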

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

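Tests of a swap of constructs, of batches and of level for base excision repair and translocation genes were chosen only after the results were seen; the tests of normalization, single arrays, level for the other lists and splits were written down first, except that the random lists matched on level were added after seeing the data.

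Results stand out here because the response to shSIRT6 differed between the lines by a test of the difference itself (limma, Benjamini-Hochberg adjusted p below 0.05 for 26 genes). On the log2 scale, NCI-H929 minus MM1.S, the difference was 2.49 for DDIT3, 2.24 for SESN2, 2.15 for TRIB3, 1.43 for ASNS, 1.22 for SARS1 and 0.96 for PSAT1. Outside the amino acid response list it was 2.16 for DDIT4, 2.55 for CCDC144CP, 2.30 for PIERCE2, 1.61 for PLXDC2, 1.55 for EFEMP1, 1.53 for CALCRL, 1.43 for ALOX5AP, 1.03 for DNAAF4-CCPG1 and −1.21 for CCND2. Levels of CALCRL in NCI-H929 were 2.75 with scramble and 2.96 with shSIRT6, under the filter level of 3.045, so a fall could not be measured there and the size of its difference is not resolved. As lists, the median difference was 0.95 for the ATF4 and amino acid response, −0.30 for mitosis, −0.32 for DNA replication, −0.32 for cholesterol synthesis and −0.41 for translocation genes. Of these 5 lists only that of ATF4 also passed with an estimated correlation (camera adjusted p = 0.0119).

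The ATF4 pattern is the one most open to follow-up. Other normalizations left the median difference at 0.94 or more (camera adjusted p at most 1.98e-21) and leaving out any 1 array left it at 0.88 or more (at most 7.11e-18), which argues against both as the cause. Turning back the constructs of one line left a median difference of −0.63 (MM1.S) or 0.63 (NCI-H929) at the smallest. This was over all arrays, the other normalizations and the fits without 1 array (over all arrays camera adjusted p = 1.78e-05, and adjusted p = 0.171 with an estimated correlation). These values restate the average over both lines, which had already passed, so they cannot show whether constructs were swapped. They show only that a swap alone would not make the list alike in both lines, and a swap stays open. For DDIT3, SESN2 and TRIB3, whose averages over both lines were 0.05, −0.09 and −0.09, a swap would remove the difference and for the list it would change which way it moved, and SIRT6, lower by −1.83 standard errors in MM1.S and −2.92 in NCI-H929 (log2 −0.47, and −0.25 without scramble replicate 2), checks the labels only weakly. A difference in culture between the constructs of a line, such as medium or density, could also move this amino acid program, and with 0 batches named in the labels it cannot be told apart from the construct. A response to SIRT6 loss that differs between the lines stays open as a hypothesis, untested beyond these arrays.

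Several lists of abundant genes were lower with shSIRT6 in NCI-H929, where shSIRT6 arrays span a narrower range (SD 2.05 and 2.04 against 2.10 and 2.09) and genes with log2 levels of 6.13 to 7.51 and 7.51 to 12.8 had median changes of −0.12 and −0.09, against 0.07 for genes at 3.05 to 3.98. Narrowing as the whole cause is argued against for mitosis and DNA replication, whose calls held after cyclic loess normalization (adjusted p = 2.66e-07 and 5.31e-08), with medians going from −0.28 to −0.20 and from −0.36 to −0.28 (−0.18 and −0.26 under quantile normalization), so that part of the falls could go with it, and whose medians lay below all of 10000 random lists matched on level (0 as low). It could account for the spliceosome core (0.689 after loess, percentile 22.4), SR proteins and hnRNPs (0.689, 6.70), double-strand break repair (0.0768, 3.43), heat shock (0.0798, 6.95) and base excision repair (0.372, 5.83), whose medians moved to −0.04, −0.03, −0.08, −0.09 and −0.09, toward the median of all genes (−0.02), and so lost their calls. For ribosomal proteins (0.144 after loess, percentile 0.61) and translocation genes (0.0335, 6.21) the 2 results part, so narrowing and a true fall cannot be told apart. For mitosis and DNA replication, neither of which passes with an estimated correlation, no biological explanation was tested.

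MM1.S showed a similar trend with level, from a median change of 0.07 for genes at 3.05 to 3.98 to −0.07 for genes at 7.51 to 12.8. There the median of the unfolded protein response list, −0.15, lay at percentile 2.72 of 10000 random lists matched on level.

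Transcript clusters without a gene name were left out of the comparisons. When all 33745 clusters past the filter were tested together, 26 unnamed clusters were called in NCI-H929 (25 higher, 1 lower) and 65 in MM1.S (2 higher, 63 lower), of 20034 unnamed ones. In that fit 50 named clusters were called in MM1.S and 3 in NCI-H929. Only 48 of the calls in MM1.S were among the 169 genes of the main fit, so the 65 do not simply add to those.

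For the 11 genes called on average over both lines, 2 of the 34 splits of the 8 arrays that could be fitted gave as many, the real one included. The other, with 26, was the highest. It turns the constructs round in one line and so measures the difference between the lines, not chance, and the other 32 gave 0. A share over 5% that rests on such a split does not decide whether chance is excluded.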

How the results depend on the processing

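Counts of called genes depended strongly on how the spread was estimated. Among the called named genes, the passing lists, SIRT6 in each line and on average, and the correlation, no value changed sign under an alternative. The shares of higher and lower calls did move. Named genes that were not called were not followed. Without scramble replicate 2 of NCI-H929, SIRT6 fell less there (−0.25) than in MM1.S (−0.295), the reverse of the fit of all arrays. Of the values of counts, correlations and SIRT6 under alternatives other than leaving out an array, 110 stayed and 55 moved, all given here. Counts stayed if they were within 1.5 times, and SIRT6 if it kept its sign and its side of the threshold. A count can stay while its members change: over every cluster MM1.S had 115 calls, of which 48 were among the 169 genes. Correlations stayed if they moved by less than the SD of the correlations over the fits without 1 array. The cause was not tested unless stated. SIRT6 kept its sign and stayed uncalled throughout, in each line and on average. List calls held in 333 and were lost in 71 of these alternatives; the ATF4 list in MM1.S and in the difference between the lines was never lost. Calls of named genes held in 563 and were lost in 167. Array signal over background was not used here, so how far dim probes limit these counts is open. All these alternatives were planned.

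The replicate block left 0 calls in MM1.S, 0 in NCI-H929, 0 on average and 0 in the difference between the lines (limma; 2444, 1806, 2649 and 1704 genes at an unadjusted p below 0.05). The numbers share no batch in the labels. Deviations of arrays with one number correlated at −0.041 to 0.077, with 0.077 between the constructs of MM1.S and −0.0011 between those of NCI-H929. Such weak correlations give no sign that the numbers pair the arrays, but they cannot exclude it. Each line fitted alone gave 0 calls in MM1.S and 0 in NCI-H929 (2275 and 1747 unadjusted), with fewer arrays to estimate the spread. Calls in NCI-H929 went to 0 under quantile normalization, cyclic loess, no filter, the mean of clusters, array weights and treat against 1.2-fold (limma; 1471, 1553, 1944, 1846, 1851 and 308 unadjusted), and to 29 over every cluster. On average over both lines they went to 4 under quantile normalization, 2 under median centring, 5 under loess, 0 over every cluster and 0 under treat (6151 and 260 unadjusted). A stricter filter, which tests fewer genes, gave 487 calls in MM1.S, 353 on average and 72 in the difference. eBayes with trend and robust options gave 948 in MM1.S, 196 in NCI-H929, 908 on average and 424 in the difference. An unadjusted p with 1.5-fold gave 431, 240, 86 and 712 in that order. Treat gave 21 in MM1.S, 10 in the difference and 2991 between the lines with scramble; every cluster gave 41 in the difference and 9504 between the lines. Higher calls made up 15.4% in MM1.S, 18.7% under quantile normalization and 13.7% under loess, but 25.7% with trend and robust, 29.9% at an unadjusted p with 1.5-fold, 5.22% over every cluster and 0% under treat. In NCI-H929 they went from 66.7% of 3 to 12.2% with trend and robust, 47.9% at an unadjusted p with 1.5-fold and 93.1% over every cluster, on average from 0% to 15.3% and 33.7% (13.3% with the stricter filter), and in the difference from 96.2% to 46.9% and 46.8% (66.7% with the stricter filter). The correlation between the lines fell to 0.108 under quantile normalization and 0.107 under loess.

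Lists passing in NCI-H929, 11 in number, became 4 under quantile normalization and 4 under loess, 0 with an estimated correlation, 17 with fry and 22 with its mixed test. On average, 10 lists became 6 and 6 (6 of the 10 were lost each time and others gained), 3 with the stricter filter, 0 with an estimated correlation, 16 with fry and 26 with the mixed test. In MM1.S, 4 became 7 over every cluster, 1 with an estimated correlation, 8 with fry and 26 mixed. In the difference, 5 became 8 with trend and robust, 1 with an estimated correlation, 14 with fry and 25 mixed.

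Leaving out 1 array at a time assumes that the lone array of its group varies like the others. MM1.S calls then ran from 0 to 84: 0 without scramble replicate 1 (1477 unadjusted) and 11 without replicate 2 of MM1.S, 7 and 0 without its shSIRT6 replicates 1 and 2 (2042 and 1877), 24 without either scramble array of NCI-H929 and 84 without either of its shSIRT6 arrays. NCI-H929 and the average had 0 calls without any 1 array (at least 1184 and 1877 unadjusted), the difference 2 to 6, and the lines with scramble 3713 to 4884. The correlation ran from 0.0971 to 0.196. Lists passing ran from 2 to 5 in MM1.S, 7 to 12 in NCI-H929, 7 to 11 on average and 5 to 6 in the difference. SIRT6 ran from −0.40 to −0.19 in MM1.S, −0.69 to −0.25 in NCI-H929 and −0.49 to −0.27 on average. Calls of named genes were lost in 243 of these fits and held in 229.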

Other observations

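Cytosolic tRNA synthetases, which charge tRNAs with amino acids, were lower in MM1.S with shSIRT6. Of 17 tested members of the family, a set drawn up after its values were seen, 16 were negative and 6 fell (AARS1, CARS1, GARS1, IARS1, SARS1 and WARS1), with a median log2 change of −0.52. SARS1 and WARS1 belong to the ATF4 list as well. Of the 15 members outside that list, 14 were negative and 4 fell, with a median of −0.485. In NCI-H929 the median over the 17 was −0.01. TXNIP, a regulator of glucose uptake, and the splicing regulators ESRP1 and MBNL2, singled out after their values were seen, differed between the lines: the log2 change of TXNIP was −1.17 in MM1.S and 0.15 in NCI-H929 (difference 1.32 ± 0.15, SE), that of ESRP1 −0.96 and 0.40 (1.36 ± 0.17) and that of MBNL2 −0.89 and 0.09 (0.98 ± 0.12), with adjusted p of 0.0323, 0.0417 and 0.0435 (limma, Benjamini-Hochberg).

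The other lists fixed in advance passed in neither line. Median log2 changes in MM1.S and NCI-H929 were −0.23 and −0.05 for p53 targets, −0.15 and −0.12 for hypoxia genes, −0.02 and −0.04 for NF-kB targets, 0.08 and 0.04 for interferon-stimulated genes, 0.01 and −0.11 for oxidative phosphorylation, and 0.07 and 0.05 for sirtuins and NAD metabolism. They were 0.10 and −0.01 for ribosome biogenesis, 0.04 and −0.10 for fatty acid synthesis, 0.16 and −0.15 for MAPK feedback genes, −0.03 and −0.08 for immediate-early genes, 0.06 and 0.00 for 608 microRNA genes, 0.10 and −0.03 for myeloid markers and 0.12 and 0.10 for kidney and epithelial markers. The lowest camera adjusted p among these was 0.0709 in MM1.S (p53 targets) and 0.0820 in NCI-H929 (oxidative phosphorylation).

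The test of neighbouring genes was chosen only after the result was seen. Of 169 genes called in MM1.S, 143 of them lower, 20 lay beside another called gene. Among tested genes in genome order, 11 neighbouring pairs were both called, against a median of 2 and at most 9 in 10000 random draws of 169 genes (permutation p = 1e-04, the smallest these draws can give), and both genes fell in all 11. The draws took tested genes of any level and were not matched to the called ones, so the excess is over unmatched draws only. A run on chromosome 15 holds RSL24D1 (−0.77), DNAAF4-CCPG1 (−1.14), MIR628 (−1.81) and PIERCE2 (−1.97). Other pairs were DDIT3 with MIR616, POLR3GL with TXNIP and RNF133 with RNF148. Genes of these pairs, microRNAs included, are named outside the rule, after their values were seen. Clusters that read one transcript, such as a microRNA inside its host gene, could give such pairs, and 4 of the 11 include a microRNA. The 7 pairs without one still exceeded the median of 2 from draws without microRNAs (permutation p = 0.0068), so microRNAs alone do not account for the excess over these unmatched draws. Readthrough transcripts and shared regulation of neighbours both stay open, as the probes' positions were not analysed here.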
